A study of Homo sapiens with 8 samples.

How the data were processed

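RNA of 8 libraries from the lung squamous carcinoma line LK2 was sequenced, per the labels' protocols, as polyA-selected, directional libraries read from both ends for 38 bp. Per the labels, cells were grown in RPMI-1640 medium with serum and carried lentiviral vectors for GFP (2 libraries), for DNp63 expressed constitutively (2) or for DNp63 under doxycycline control (2 libraries without the drug and 2 with it). The GFP and DNp63 libraries of the same replicate number share a vector number, 306 or 307. The labels do not say whether the 2 libraries of a group come from separate cultures of cells infected separately.

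The deposited values are raw counts per gene, 1 column per library. Per the submitters' processing notes, reads were aligned with TopHat2 2.1 to the hg19 human genome and the authors counted reads per gene with HTSeq after handling the alignments with SAMtools, and used DESeq2 for differential expression. The annotation version, the strand setting of the counting and any filter are not given in the sources used here. All deposited values were checked to be whole numbers of 0 or more, which is what a count table holds. The table has 26760 genes named by symbol, of which 23232 matched a current symbol in the reference name table and 25519 matched a current or older one. The reference annotation at hand is of another genome build, so no coordinates are given, and genes are named by the symbols of the table.

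Genes were kept for testing by edgeR's filterByExpr on the 4 groups with a minimum count of 10, which left 12303 genes. Library sizes were scaled by the trimmed mean of M-values. A model with a mean for each of the 4 groups and a spread shared by all 8 libraries was fitted with edgeR 4.0.16 (quasi-likelihood, legacy estimates) under R 4.3.3. Tests were two-sided quasi-likelihood tests with Benjamini-Hochberg adjustment over all tested genes, and a gene was called at an adjusted p below 0.05. Standard errors of log2 fold changes came from the same fit. The contrasts were the average of both systems' DNp63 effects, each system's effect, the difference between them (induced minus constitutive) and the difference between the control groups (uninduced minus GFP). CPM values use the scaled library sizes, and figures on the log scale use a prior count of 2. Groups with 0 to 3 counts for a gene are compared by the ratio of summed counts with a 95% exact interval, or, at 0 counts, by a lower bound that puts the group at a floor of 3 counts over the group. TP63 counts as a share of total counts carry 95% exact binomial limits. Such intervals and floors cover counting error only. In a single library 3 counts correspond to 0.289 to 1.09 CPM, and library totals of 2758158 to 10372248 counts limit what can be seen of weakly expressed genes.

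The comparisons, the test with its filter and scaling, the alternatives except those said below to be added later, the gene lists and the rule for named genes were fixed before the data were examined. The legacy estimates, the treatment of groups with few counts and the list tests for the difference and for the control groups were set later. Of 28 lists, 25 had at least 3 measured members: squamous and basal epithelial markers, epithelial junction and identity genes, hemidesmosome and basement membrane genes, cornification genes, reported direct p63 targets, neural progenitor and neural transcription factor genes, neuronal and neuroendocrine markers, mesenchymal markers, cell cycle genes, p53 target genes, interferon-stimulated genes, antigen presentation genes, Notch, Wnt and growth factor receptor signalling genes, NRF2 targets, ATF4 stress response genes, nuclear respiratory chain genes, hypoxia and glycolysis genes, cholesterol synthesis genes, immediate early genes, heat shock genes, ribosomal protein genes, histone genes and markers of other lung epithelial cells. Mitochondrially encoded genes, fibroblast markers and immune and endothelial markers were listed but had too few measured members. TP63 is in no list, and some genes are in more than 1 list, such as ITGA3 and ITGB4. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the 25 lists. Members were also tested with adjustment over the list alone.

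The rule for named genes had these parts. (a) TP63, SOX2, POU3F2 and TP73 were named whatever their result. (b) In the averaged comparison the 8 largest rises and 8 largest falls were named among called genes with a mean of at least 5 CPM and the same sign in each of the 4 numbered pairs of a control and a DNp63 library, without clone or locus names. (c) Each list gave up to 4 measured members with the smallest p in the averaged comparison. (d) Each system gave the 4 largest rises and 4 largest falls among called genes with a mean of at least 5 CPM and no overlap between the groups. (e) The difference between systems gave the 5 called genes with the smallest adjusted p. (f) The control groups gave up to 3 genes each way chosen as in d. Genes named outside this rule are said to be chosen after their values were seen.

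Simulated data were drawn 10 times with the real library sizes, 200 genes changed and 12042 genes tested on average. Each gene had a mean and a spread that were estimated from all 8 libraries and equal in both systems. The fit was tested on these data. For constitutive DNp63 it recovered 27.5% of 2-fold and 88.2% of 4-fold changes with 5.63% of calls false, and for induced DNp63 30.8% and 89.2% with 7.48% false. For the averaged comparison 7.26% of calls were false. The contrasts for the difference and for the control groups, simulated with no change, gave 6 calls each over the 10 runs. These rates hold for an equal spread and need not hold for the real data. There the common dispersion was 0.0817 for the constitutive and 0.0103 for the inducible libraries fitted alone. Fits to the 4 libraries of a single system were tested in the same way, with means and spreads estimated from those libraries. They recovered 8.8% of 2-fold and 70.9% of 4-fold changes for the constitutive libraries, with 11.5% of calls false, and 84.6% and 99.4% for the inducible libraries, with 4.07% false.

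The alternatives tried were median-of-ratios scaling, library totals alone, no low-count filter, a stricter filter with a minimum count of 50, DESeq2 1.42.0, limma-voom, each numbered pair of a control and a DNp63 library within a system as a block, an added minimum log2 fold change of 1, TP63 left out before scaling, each library left out in turn, models with no term or an additive term for the system, and each system fitted alone. Leaving a library out leaves its group with 1 library, which is then assumed to vary like the others. Alternatives added after seeing the data were the newer quasi-likelihood estimates of edgeR, leaving out both first-numbered constitutive libraries, and values within each numbered pair of libraries. Other splits of the libraries into 4 and 4 were counted once each. Sequence shared between genes was measured as 38-base stretches, the read length, of reference transcripts found in another gene's transcripts. Ratios and exact intervals were computed in R, and figures with matplotlib 3.10.9 under Python 3.11.15. No library was left out of the main comparisons.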

Results

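Gene counts were measured by RNA sequencing in 8 libraries of LK2, a human lung squamous carcinoma cell line. The libraries fell into 4 groups of 2. In the constitutive system, cells carried a vector for GFP, the control, or for DNp63, the form of the transcription factor p63 that lacks its N-terminal activation domain. In the inducible system, cells carried a DNp63 vector controlled by doxycycline, and were compared after 6 days with the drug at 2 µg per ml (induced) or without it (uninduced). The total count was 2758158 and 4819186 in the GFP libraries, replicates 1 and 2. It was 3348421 and 4924534 in the constitutive DNp63 libraries. The uninduced libraries held 5067659 and 10372248 counts, and the induced libraries 8169745 and 5229957. Of 26760 genes in the table, 8601 had no count in any library and 12303 had enough counts to be tested. The title of the series names SOX2, a transcription factor of lung squamous tumours, and BRN2, a neural transcription factor encoded by POU3F2. The comparisons ask which genes differ when DNp63 is overexpressed in these cells, and how SOX2, POU3F2 and genes of squamous and neural identity stand among them.

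TP63, the overexpressed gene, was highest in the libraries labelled as DNp63 cells, in both systems. Its level was 0.739 and 1.91 CPM, counts relative to library size, in the GFP libraries and 1850.1 and 3816 CPM in the constitutive DNp63 libraries. It was 12.7 and 14.8 CPM in the uninduced libraries and 412 and 422 CPM in the induced libraries. The log2 fold change of TP63 was 10.90 ± 0.50 (SE, n = 2 per group) under constitutive DNp63, with an adjusted p of 3.87e-06. Under induced DNp63 it was 4.91 ± 0.36, with an adjusted p of 0.000239. Averaged over both systems it was 7.91 ± 0.31, with an adjusted p of 6.92e-07. TP63 thus reached 417 ± 6.89 CPM (SD, n = 2) in induced cells against 2833 ± 1389.9 CPM in constitutive DNp63 cells. The constitutive SD is between libraries with different vector numbers, and the induced SD between libraries with the same vector number. Before induction, 63 and 152 TP63 counts were present in the uninduced libraries, against 2 and 9 in the GFP libraries. As CPM of unscaled totals these were 12.4 (95% limits 9.55 to 15.9) and 14.7 (12.4 to 17.2) uninduced, and 0.725 (0.0878 to 2.62) and 1.87 (0.854 to 3.55) with GFP. The limits do not overlap, but the control groups' log2 difference of 3.23 ± 0.50 did not pass the test across all genes, with an adjusted p of 0.165. It passed without DNp63 replicate 1, with an adjusted p of 0.00826, and without DNp63 replicate 2, with 0.00686. TP63 counts include reads of the vector wherever these match the gene.

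**Figure D1:**
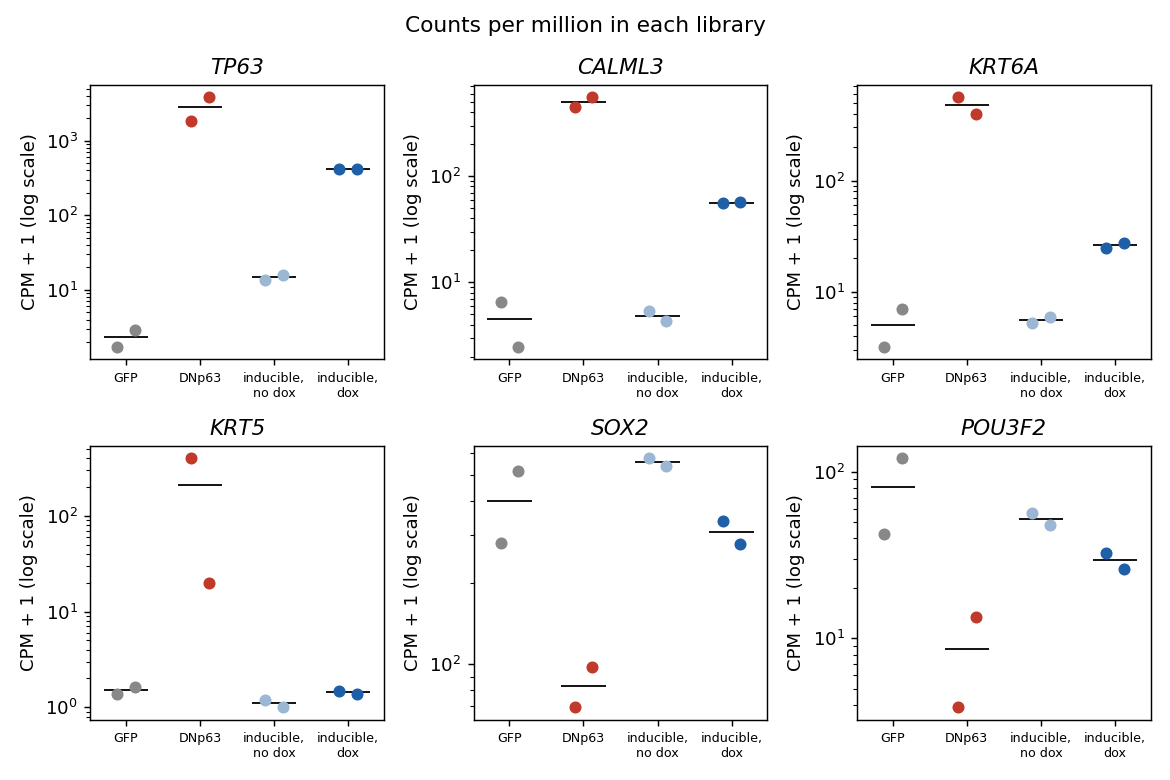
CPM plus 1, on a log scale, of 6 genes in each of the 8 libraries, with points for libraries and lines for the group means. TP63 is at 1850.1 and 3816 CPM in constitutive DNp63 libraries and at 412 and 422 CPM in induced libraries, and the mean of SOX2 falls from 398 CPM with GFP to 82.3 CPM with constitutive DNp63.

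In the averaged comparison of DNp63 cells with the controls of their own system, markers of squamous epithelium rose, while SOX2 and POU3F2 fell. CALML3, a calmodulin-like protein of stratified epithelium, had a log2 fold change of 5.60 ± 0.27 (SE, n = 2 per group; adjusted p = 2.35e-06). It was at 3.51 ± 2.87 CPM (SD, n = 2) with GFP and 501 ± 71.2 CPM with constitutive DNp63, and at 3.87 ± 0.793 CPM uninduced and 55.5 ± 0.552 CPM induced. KRT6A, a keratin of stratified and wounded epithelium, rose by 4.58 ± 0.24 on the log2 scale (adjusted p = 3.45e-06), although the counts could divide its reads with the near-identical KRT6B and KRT6C. SOX2 fell by 1.56 on the log2 scale, with an SE of 0.20 and an adjusted p of 0.0013. Its mean was 398 ± 169 CPM with GFP and 82.3 ± 19.9 CPM with constitutive DNp63, and 556 ± 27.0 CPM uninduced and 307.3 ± 42.1 CPM induced. POU3F2 had a log2 fold change of −2.09 ± 0.38 (adjusted p = 0.00951), a call that was lost without induced replicate 1 (0.0764) or induced replicate 2 (0.0751). The p63 relative TP73, at −0.12 ± 0.22, did not pass the test (adjusted p = 0.829).

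Among the largest rises by the rule for named genes, 6 had 3 or fewer counts in a control group and are given as ratios with 95% counting intervals. CLCA2, a chloride channel regulator of stratified epithelium, had 798 counts with constitutive DNp63 and 1 with GFP, a ratio of 685 (123 to 27086). It had 53 counts induced and 0 uninduced, at least 20.4-fold higher. The cilium-associated adenylate kinase gene AK8 had a ratio of 505 (139 to 4172) under constitutive DNp63. The phosphodiesterase gene PDE7B had 169 counts with constitutive DNp63 and 0 with GFP, at least 48.3-fold higher. Its induced log2 fold change of 1.11 did not pass the test (adjusted p = 0.858). CST7, a cysteine protease inhibitor, had a ratio of 62.7 (21.2 to 306.2) under constitutive and 25.5 (4.12 to 1050.9) under induced DNp63. DBH, the enzyme that makes noradrenaline, had a ratio of 44.9 (15.1 to 220.1) under constitutive DNp63. Its antisense partner DBH-AS1 had 59.8 (20.2 to 292) there and 381 (105 to 3151) under induced DNp63. The reads of DBH and DBH-AS1 cannot be told apart, since the strand setting of the counting is not given in the sources used here. Among the largest falls, MOBP, a myelin protein gene, had a log2 fold change of −3.47 ± 0.26 (SE; adjusted p = 3.79e-05). OTOP1, a proton channel, had −2.98 ± 0.19 (adjusted p = 1.43e-05) and ADH1C, an alcohol dehydrogenase, −2.99 ± 0.29 (adjusted p = 0.000224). The collagen gene COL8A1 had −2.996 ± 0.29, the neuronal pentraxin gene NPTX1 −2.94 ± 0.41 and SHISA2 −2.92 ± 0.31. GRIK3, a kainate receptor subunit, had 3 counts with constitutive DNp63, all in replicate 1, and 288 with GFP, a ratio of 0.00894 (0.00183 to 0.0264). The matrix gene THBS1 had −3.11 ± 0.66 (adjusted p = 0.0208). The THBS1 call was lost without GFP replicate 2 (adjusted p = 0.166), where its value was −1.60, and without uninduced replicates 1 (0.0611) or 2 (0.0686), or induced replicates 1 (0.11) or 2 (0.121). The other 7 falls and all 8 rises passed the test with each library left out in turn.

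Of the gene lists, the squamous and basal epithelial markers moved furthest. Among 17 measured members 9 rose, including CALML3, KRT6A and TRIM29 (2.64 ± 0.26 on the log2 scale), and 7 did not pass the test. The 1 that fell, FGFBP1 (−1.21 ± 0.19), is a secreted binding protein for fibroblast growth factors and was chosen after its values were seen. Adjusted over the list alone, 14 rose and 2 fell. The list median was 2.64, or 1.70 with the low-count genes at their bounds, and the list test gave an adjusted p of 4.69e-24, or adjusted p = 0.00888 with an estimated correlation. The reported direct p63 targets also rose as a list, with 10 of 29 members higher, among them the ectodysplasin receptor EDAR (4.81 ± 0.39) and the laminin receptor subunits ITGA3 (2.01 ± 0.18) and ITGB4 (1.77 ± 0.24). The single fall, in HAS3, a hyaluronan synthase, was by 2.58 on the log2 scale, with an SE of 0.18. Adjusted over the list alone, 12 rose and 3 fell, and the test gave an adjusted p of 7.84e-06 and adjusted p = 0.0645 with an estimated correlation. Of 21 hemidesmosome and basement membrane genes, which anchor epithelium to its matrix, 6 rose and 2 fell (9 and 3 adjusted over the list alone; adjusted p = 0.00034, and adjusted p = 0.309 with an estimated correlation). PLEC, the linker protein plectin, rose by 1.10 ± 0.15 on average, with 1.97 constitutive and 0.24 induced, the latter not called. The falls were in the laminin chain LAMC1 (−0.95 ± 0.18) and the type IV collagen chain COL4A2 (−0.75 ± 0.15, chosen after its values were seen). Cornification genes, which build the outer layer of skin, had 2 of 5 members higher and none lower, PPL, the periplakin gene, at 1.18 ± 0.19 and FLG, the filaggrin gene, at 2.46 ± 0.45. Adjusted over the list alone 3 rose, the list median was 1.18 and 0.76 with low-count genes at their bounds, and the test gave an adjusted p of 0.000677 and adjusted p = 0.203 with an estimated correlation. LAMC1, COL4A2 and FLG lost their calls without uninduced replicate 2 (adjusted p = 0.0622 to 0.0729) or induced replicates 1 (0.0774 to 0.116) or 2 (0.0573 to 0.0908), and COL4A2 also without uninduced replicate 1 (0.0992).

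Neural progenitor and neural transcription factor genes fell as a list, with 3 of 16 members lower, none higher and 13 not passing the test. Adjusted over the list alone 4 fell, the median was −0.29, and the test gave an adjusted p of 0.00258 and adjusted p = 0.24 with an estimated correlation. Besides SOX2 and POU3F2, the third was NES, an intermediate filament gene of neural stem cells, at −1.34 ± 0.28 (adjusted p = 0.019). The POU3F2 call was lost without induced replicates 1 (adjusted p = 0.0764) or 2 (0.0751). The NES call was lost without uninduced replicates 1 (0.0881) or 2 (0.0772) or induced replicates 1 (0.0731) or 2 (0.0932). The 15 neuronal and neuroendocrine markers were not called as a list (adjusted p = 0.293), although DPYSL3, a growth cone protein gene (−1.20 ± 0.16), and the neurofilament gene NEFL (−0.93 ± 0.17) fell. Within the list alone 3 rose and 4 fell, and the NEFL call was lost without uninduced replicate 1 (0.0602) or induced replicates 1 (0.0797) or 2 (0.0578). Mesenchymal markers had 5 of 11 members higher and 1 lower. The cadherin gene CDH11 (3.52 ± 0.35), fibronectin, FN1 (1.61 ± 0.20), the transcription factors SNAI2 (2.72 ± 0.42) and TWIST1 (0.71 ± 0.18) and the protease gene MMP2 (0.91 ± 0.16) rose, and the neural cadherin CDH2 fell by 1.38 on the log2 scale. MMP2 and TWIST1 were chosen after their values were seen. Their calls were lost without uninduced replicates 1 (0.0518 and 0.227) or 2 (0.0569 and 0.15), and TWIST1 also without GFP replicate 2 (0.136), DNp63 replicate 1 (0.0715) or induced replicates 1 (0.233) or 2 (0.116). Adjusted over that list alone 7 rose and 3 fell, with an adjusted p of 0.000677 for the list and adjusted p = 0.3 with an estimated correlation.

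Cell cycle genes fell, with 8 of 28 members lower, none higher and a median of −0.52. RRM2, a subunit of ribonucleotide reductase, had −1.33 ± 0.19 (adjusted p = 0.00201). With adjustment over the list alone 11 fell, and the list test gave an adjusted p of 2.02e-08 and adjusted p = 0.454 with an estimated correlation. Of 26 p53 target genes 2 fell, also when adjusted over the list alone, with a median of −0.38 and −0.39 with low-count genes at their bounds. TP53I3, a quinone oxidoreductase gene, had −1.31 ± 0.19 and the nuclease gene AEN, which was called at an adjusted p of 0.0331, had −1.11 ± 0.26. The p53 list had an adjusted p of 0.00415, of 0.0693 without GFP replicate 1, and adjusted p = 0.3 with an estimated correlation. The AEN call was lost without GFP replicate 1 (0.0647), uninduced replicates 1 (0.123) or 2 (0.102) or induced replicates 1 (0.184) or 2 (0.134). Of 15 Wnt pathway genes 2 rose and 1 fell (6 and 2 adjusted over the list alone), the ligand WNT5A by 1.31 ± 0.15, the Wnt antagonist APCDD1 by 1.86 ± 0.24 and the antagonist SFRP1 at −1.03 ± 0.19. SFRP1 was not called without uninduced replicate 2 (0.0643) or induced replicates 1 (0.0732) or 2 (0.0684). The Wnt list had an adjusted p of 0.0371, which was 0.155 without GFP replicate 1, 0.0755 without uninduced replicate 2, 0.0547 without induced replicate 2, and adjusted p = 0.459 with an estimated correlation. Genes of the ATF4 stress response had a median of 0.44, with 21 of 24 members positive and 1 called, the stress protein gene NUPR1 (1.11 ± 0.27; adjusted p = 0.0355; also 1 adjusted over the list alone). NUPR1 was called only with all libraries or without a DNp63 replicate, with adjusted p values from 0.076 (without GFP replicate 1) to 0.179 (without uninduced replicate 2) in the other leave-outs and a value of 0.74 without DNp63 replicate 1. The ATF4 list had an adjusted p of 0.00322, which was 0.367 without GFP replicate 2, 0.2 without DNp63 replicate 1, and adjusted p = 0.653 with an estimated correlation. Within both constitutive groups this list was higher in replicate 1 than in replicate 2, by a median of 1.71 with GFP and 1.12 with DNp63 on the log2 scale.

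No member of the nuclear respiratory chain (29 genes), cholesterol synthesis (20) or ribosomal protein (40) lists passed the edgeR test, over all genes or adjusted over the list alone, while their medians were −0.29, −0.44 and −0.27. The list tests gave adjusted p values of 0.0016, 0.00176 and 6.79e-05, and adjusted p = 0.38, 0.617 and 0.459 with an estimated correlation. The cholesterol list was not called without GFP replicate 2 (adjusted p = 0.219) or DNp63 replicate 1 (0.118). Lists with no call were growth factor receptor signalling (20 genes; adjusted p = 0.12), in which 5 members rose, named below, and none fell. The growth factor list had a median of −0.03 although its test pointed up, and it was called without GFP replicate 2 (0.0408). Epithelial junction and identity genes (25 genes; adjusted p = 0.693) held 1 rise, of the transcription factor OVOL1 (2.46 ± 0.29), and 1 fall, of ELF3, by 1.54 on the log2 scale. NRF2 target genes (21; adjusted p = 0.847) had 2 members higher and 2 lower, named below, and a median of 0.12 with a test that pointed down. The heat shock genes (13; adjusted p = 0.249) had 2 members higher, of which the chaperone HSP90AA1 rose by 1.03 ± 0.14. Markers of other lung epithelial cells (7; adjusted p = 0.144) had 1 lower, the endoderm transcription factor FOXA2, at −1.86 ± 0.21. Notch pathway (14; adjusted p = 0.249), immediate early (16; 0.848), hypoxia and glycolysis (20; 0.847), histone (8; 0.375), antigen presentation (9; 0.847) and interferon-stimulated genes (13; 0.375) were not called as lists. The interferon list was called without DNp63 replicate 2 (0.0412). Mitochondrially encoded genes were not among those tested, and fibroblast markers (1 measured) and immune and endothelial markers (2) were too few for a list test. The fibroblast collagen gene COL1A1 had a log2 fold change of −0.07 (adjusted p = 0.925), and the macrophage marker CD68 −0.46 (adjusted p = 0.789). The endothelial receptor gene KDR had 14 counts with GFP and 0 with constitutive DNp63, at least 5.44-fold lower.

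Of the growth factor genes TGFA, a ligand of the epidermal growth factor receptor, rose by 1.35 ± 0.20, IGF1R by 0.95 ± 0.19, ERBB2 by 0.74 ± 0.17, IGFBP3 by 0.93 ± 0.23 and HBEGF, chosen after its values were seen, by 1.62 ± 0.41. Of the NRF2 targets the heme oxygenase gene HMOX1 (1.25 ± 0.27) and the ferritin gene FTH1 (0.90 ± 0.21) rose, and ALDH3A1, an aldehyde dehydrogenase (−1.77 ± 0.20), and the transketolase gene TKT (−0.52 ± 0.13) fell. The other heat shock gene that rose was BAG3 (0.64 ± 0.17). In the Notch list JAG1 rose (1.16 ± 0.25) and LFNG fell (−0.86 ± 0.14), in the hypoxia list NDRG1 rose (1.82 ± 0.41), and in the immediate early list JUNB rose (0.77 ± 0.18) and JUN (−0.56 ± 0.14) and KLF4 (−0.91 ± 0.15) fell. The averages of LFNG (−1.70 constitutive, −0.02 induced) and JUN (−1.37 and 0.24) cover systems that differed, and neither induced change was called. The histone, antigen presentation and interferon lists had no called member. Without uninduced replicate 1 the calls of IGF1R, ERBB2, IGFBP3, HBEGF, HMOX1, FTH1, TKT, JAG1, NDRG1, JUN, JUNB and BAG3 were lost (adjusted p from 0.0716 for IGF1R to 0.241 for TKT). The same 12 calls were lost without uninduced replicate 2 (0.0872 for IGF1R to 0.184 for IGFBP3), induced replicate 1 (0.0725 for NDRG1 to 0.248 for TKT) or induced replicate 2 (0.0654 for IGF1R to 0.201 for BAG3). LFNG and KLF4 lost theirs without induced replicates 1 (0.0505 and 0.0711) or 2 (0.0528 and 0.0537). Without GFP replicate 1 the calls of TKT (0.0529), HBEGF (0.0745), JAG1 (0.0575), JUNB (0.0586) and BAG3 (0.0701) were lost. Without GFP replicate 2 those of HMOX1 (0.0745), FTH1 (0.0996), TKT (0.0751), ERBB2 (0.0807), IGFBP3 (0.0702), HBEGF (0.135), NDRG1 (0.104) and JUN (0.104) were lost. Without DNp63 replicate 1 IGFBP3 was not called (0.0616) and FTH1 had 0.58, and without DNp63 replicate 2 HBEGF (0.113) and BAG3 (0.0581) were not called and JAG1 had 0.76.

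Over all 12303 genes, 697 were called in the averaged comparison at an adjusted p below 0.05, 401 higher and 296 lower, in edgeR's two-sided quasi-likelihood test. The number called was 440 without GFP replicate 2, 292 and 240 without uninduced replicates 1 and 2, 1112 without DNp63 replicate 2, and 224 and 295 without induced replicates 1 and 2. On simulated data with 200 changed genes and an equal spread in both systems, the same fit recovered 69.2% of 2-fold and 98.1% of 4-fold changes for this comparison.

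**Figure D2:**
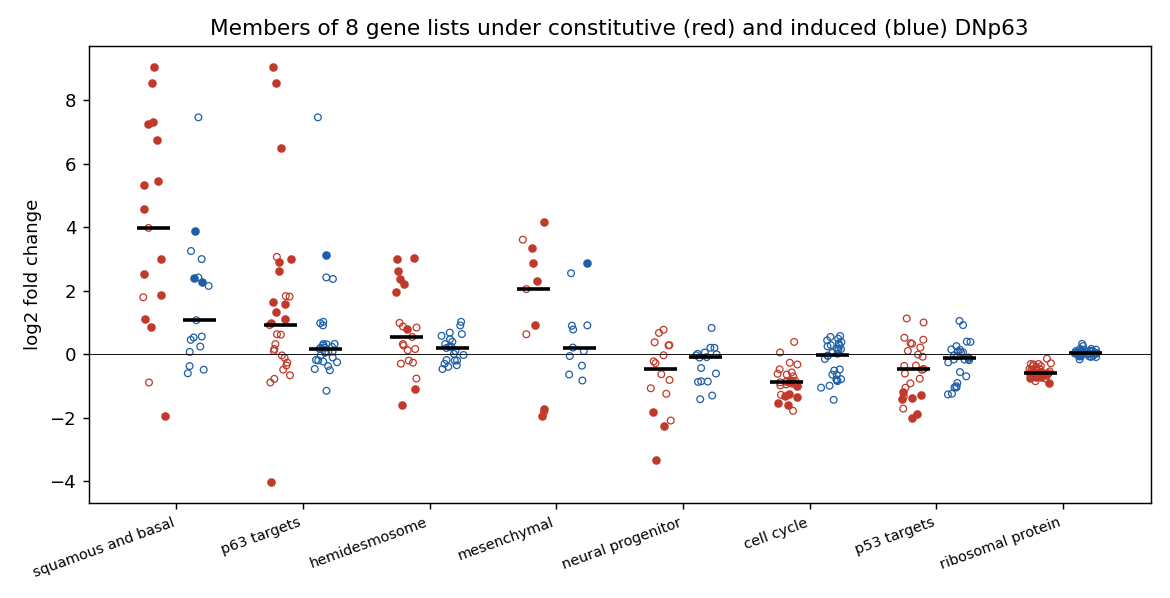
Log2 fold change of each measured member of 8 gene lists under constitutive DNp63 (red) and induced DNp63 (blue), with filled points for called genes and bars for list medians. The squamous markers have a median of 3.99 under constitutive DNp63 and 1.08 under induced DNp63, while the neural progenitor list has medians of −0.45 and −0.09.

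Constitutive DNp63 was compared with GFP to show the response to the higher TP63 level. Squamous markers rose strongly and SOX2, POU3F2, FOXA2 and ALDH3A1 fell. CALML3 rose by 7.33 ± 0.41 on the log2 scale (adjusted p = 6.63e-06) and KRT6A by 6.75 ± 0.36 (adjusted p = 6.63e-06). KRT5, the main keratin of basal cells, was at 0.502 ± 0.188 CPM (SD, n = 2) with GFP and 208 ± 268 CPM with DNp63, a log2 fold change of 8.53 ± 1.49 (adjusted p = 0.00641). Without DNp63 replicate 1 the KRT5 value was 5.09, and without GFP replicate 2 its call was lost (adjusted p = 0.0871). SOX2 had a log2 fold change of −2.27 ± 0.30 (adjusted p = 0.00125) and POU3F2 −3.34 ± 0.58 (adjusted p = 0.00589). HAS3 had −4.02 ± 0.27, FOXA2 −3.01 ± 0.31 and ALDH3A1 −3.09 ± 0.30. The largest changes by the rule were in TP63, in the low-count genes CLCA2, PDE7B and GRIK3 and in the genes that follow. GRIA1, a glutamate receptor subunit, had 367 counts with DNp63 and 0 with GFP, at least 105-fold higher. ADH1C had −4.93 ± 0.46 (adjusted p = 0.000218), and PTX3, a secreted pattern recognition protein, −4.48 ± 0.77 (adjusted p = 0.00589). Without DNp63 replicate 2 the PTX3 value was −7.13. RPPH1, the RNA of ribonuclease P, had −4.32 ± 1.13 (adjusted p = 0.0421) and was called only when all 8 libraries were in the fit or GFP replicate 2 was left out. Without GFP replicate 1 the RPPH1 value was −1.58. Without GFP replicate 1 its adjusted p was 0.373, without uninduced replicates 1 and 2 it was 0.0539 and 0.054, without DNp63 replicates 1 and 2 it was 0.118 and 0.0899, and without induced replicates 1 and 2 it was 0.0844 and 0.0847. Apart from TP63 and the largest changes, the genes of this paragraph were chosen after their values were seen.

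Squamous and basal markers had 13 of 17 members higher and 1, FGFBP1, lower under constitutive DNp63 (15 and 2 adjusted over the list alone), with a median of 3.99 and of 3.003 with low-count genes at their bounds. The test gave an adjusted p of 1.93e-21 and adjusted p = 0.0111 with an estimated correlation. The p63 targets had 11 of 29 higher and 1, HAS3, lower (16 and 4 adjusted over the list alone; adjusted p = 8.53e-06, and adjusted p = 0.0724 with an estimated correlation). Of the 21 hemidesmosome and basement membrane genes 7 rose, among them ITGA3 (3.001 ± 0.27), ITGB4 (2.62 ± 0.35) and the anchoring collagen gene COL7A1 (3.03 ± 0.42), and 2 fell, LAMC1 (−1.60 ± 0.26) and COL4A2 (−1.10 ± 0.21; adjusted p = 0.0108, and 0.0574 without GFP replicate 2). With adjustment over the list alone 9 rose and 3 fell, with an adjusted p of 0.000131 and adjusted p = 0.287 with an estimated correlation. Ribosomal protein genes had 11 of 40 members lower and none higher (31 lower adjusted over the list alone), a median of −0.60, and an adjusted p of 1.15e-09, with adjusted p = 0.391 with an estimated correlation. They made up 7.63% and 8.04% of all counts in the constitutive DNp63 libraries against 12.04% and 10.02% with GFP. The nuclear RNA MALAT1 was higher in the same libraries, at 261 and 284 CPM with constitutive DNp63 against 132 and 177 CPM with GFP. Whether a difference in RNA make-up or quality lowered the ribosomal protein counts was not tested. Cell cycle genes had 8 of 28 members lower (18 adjusted over the list alone) and a median of −0.88, with the anaphase activator CDC20 at −1.35 ± 0.22. The cell cycle list had an adjusted p of 8.56e-09 and adjusted p = 0.417 with an estimated correlation. Cholesterol synthesis genes had 6 of 20 members lower (11 adjusted over the list alone), a median of −0.92, and an adjusted p of 3.58e-06, with adjusted p = 0.455 with an estimated correlation. Respiratory chain genes had 5 of 29 lower (9 adjusted over the list alone), with the succinate dehydrogenase subunit SDHA at −0.90 ± 0.18, an adjusted p of 5.91e-06 and adjusted p = 0.267 with an estimated correlation. ATP5B, NDUFA9 and COX4I1, also lower, lost their calls with any library left out (adjusted p = 0.0503 to 0.179) except DNp63 replicate 1 for ATP5B, DNp63 replicate 2 for COX4I1, GFP replicate 2 for NDUFA9 and GFP replicate 1 for COX4I1. The p53 targets had 6 of 26 lower (8 adjusted over the list alone), a median of −0.47 and an adjusted p of 0.0116, which was 0.223 without GFP replicate 1 and adjusted p = 0.287 with an estimated correlation. Of the other lists called here, cornification genes rose (3 of 5 members, PPL, FLG and CRNN; adjusted p = 1.62e-05, and adjusted p = 0.0791 with an estimated correlation) and neural progenitor genes fell (3 of 16, SOX2, POU3F2 and NES; adjusted p = 0.00676, and adjusted p = 0.267 with an estimated correlation). CRNN was not called without GFP replicate 2 (0.0789), and NES was called only with all libraries or without DNp63 replicate 2 (0.0584 to 0.0809 in the other leave-outs). Mesenchymal markers (adjusted p = 0.00811), with CDH11 at 4.17 ± 0.50 and CDH2 at −1.93 ± 0.27, and ATF4 genes (adjusted p = 7.79e-05) had adjusted p = 0.391 and 0.591 with an estimated correlation. The mesenchymal call was lost without GFP replicate 2 (0.36), and the ATF4 call without GFP replicate 2 (0.266) or DNp63 replicate 1 (0.0889). Apart from SOX2 and POU3F2, the single genes of this paragraph were chosen for it after their values were seen. The spread shared by all 8 libraries was smaller than that of the constitutive libraries fitted alone (common dispersion 0.0448 against 0.0817). Constitutive adjusted p values may therefore be too small. The constitutive spread also includes any difference between the vectors of the replicates, whose vector numbers differ. In total 1004 genes were called, 513 higher and 491 lower. The number was 451 without GFP replicate 2, 583 and 594 without uninduced replicates 1 and 2, 609 and 612 without induced replicates 1 and 2, and 282 when only the 4 constitutive libraries were fitted.

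Induced DNp63 was compared with uninduced cells of the same line. CALML3 rose by 3.88 ± 0.36 on the log2 scale (adjusted p = 0.0012), and KRT74, a hair follicle keratin, rose from 10.9 ± 0.854 CPM (SD, n = 2) to 116 ± 18.3 CPM, by 3.40 ± 0.23 (adjusted p = 0.000239). KRT6A rose by 2.42 ± 0.32 and TRIM29 by 2.28 ± 0.37, while SOX2 and POU3F2, each at a log2 fold change of −0.85, did not pass the test (adjusted p = 0.464 and 0.945). These genes were chosen after their values were seen. SOX2 was at 337 and 278 CPM induced against 575 and 537 uninduced, and POU3F2 at 31.7 and 25.2 against 55.7 and 47.2. The shared spread was larger than that of the inducible libraries alone (common dispersion 0.0448 against 0.0103). Their missing calls therefore do not show that these 2 genes were unchanged. By the rule, the largest rises were in DBH-AS1 and DBH, whose reads cannot be told apart, in TP63 and in the actin-associated gene PALMD. DBH had a log2 fold change of 5.31 ± 0.88 (adjusted p = 0.0411) and PALMD 4.33 ± 0.74 (adjusted p = 0.0458). The largest falls were in MOBP (−2.78 ± 0.32; adjusted p = 0.00628), OTOP1 (−2.10 ± 0.25; adjusted p = 0.00834), the retinaldehyde dehydrogenase gene ALDH1A1 (−1.49 ± 0.22; adjusted p = 0.0238) and the Wnt receptor gene FZD1 (−1.38 ± 0.23; adjusted p = 0.0412). The squamous list had 3 of 17 members higher (4 adjusted over the list alone) and a median of 1.08, or 0.56 with low-count genes at their bounds. It had an adjusted p of 2.59e-13 and adjusted p = 0.0282 with an estimated correlation. The p63 targets (adjusted p = 0.0146) and mesenchymal markers (0.00165) had 1 member higher each, EDAR and CDH11, and were called upward with Wnt (0.00165), growth factor receptor (0.0146) and Notch pathway genes (0.0401), which had none. Cell cycle (0.0052), neural progenitor (0.0442), neuronal (0.0346) and p53 target genes (0.0442) were called downward with no member passing the test over all genes. The cell cycle list did not shift as a whole, since 14 members were positive and 14 negative with a median of −0.01, and 8 were lower when adjusted over the list alone. With an estimated correlation none of these 9 calls held, and their lowest value was adjusted p = 0.288 with an estimated correlation. In the leave-outs, the neural progenitor list was lost without uninduced replicate 1 (0.273), DNp63 replicate 2 (0.0517) or induced replicate 2 (0.144) and the p53 list without uninduced replicate 1 (0.0742) or induced replicates 1 (0.209) or 2 (0.0582). The Notch list was lost without uninduced replicate 2 (0.168) or induced replicates 1 (0.0827) or 2 (0.0631), and the neuronal list without induced replicates 1 (0.0616) or 2 (0.0655). Without induced replicate 2 the p63 target, growth factor (0.0582 for both) and cell cycle (0.0607) lists were lost as well. TP63 and KRT74 remained called with each library left out. The other genes with values here lost their calls without uninduced replicate 1 (adjusted p from 0.0794 for MOBP to 0.492 for FZD1, but not CALML3 or DBH-AS1), uninduced replicate 2 (0.117 for CALML3 to 1.00 for PALMD), induced replicate 1 (0.0592 for DBH-AS1 to 0.631 for FZD1, but not CALML3) or induced replicate 2 (0.0829 for DBH-AS1 to 0.427 for FZD1, but not CALML3), and PALMD also without GFP replicate 2 (0.0521). The induced call of CDH11 was lost without either GFP (0.0709 and 0.0754), uninduced (0.596 and 0.658) or induced replicate (0.462 and 0.276).

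Over all genes 35 were called under induced DNp63, 29 higher and 6 lower. Doxycycline itself differed between these groups, so its effect and that of DNp63 cannot be told apart here. The number called was 5 and 2 without uninduced replicates 1 and 2, 4 without either induced replicate, 100 without DNp63 replicate 1 and 82 without DNp63 replicate 2. It was 803 when only the 4 inducible libraries were fitted.

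**Figure D3:**
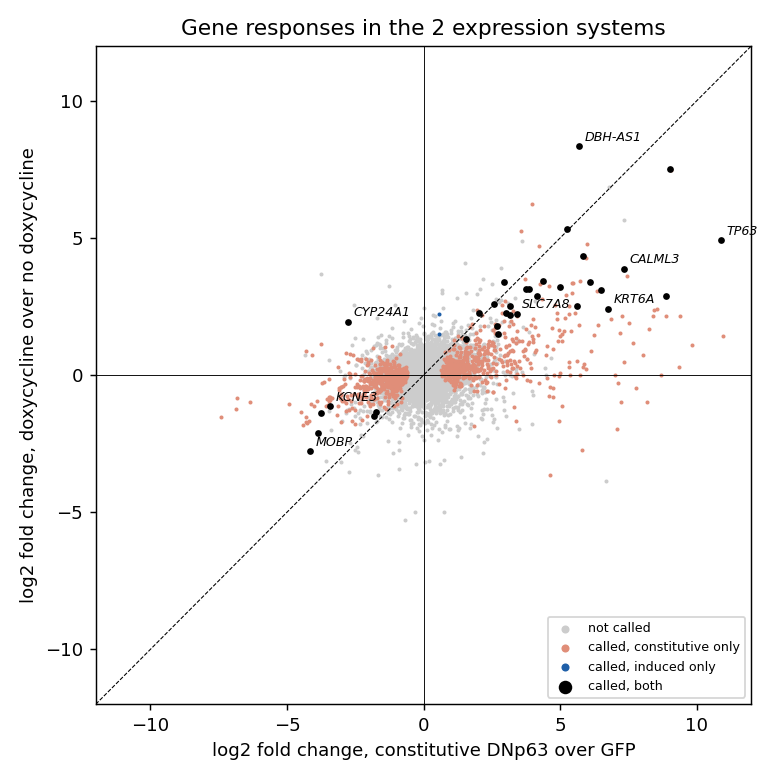
Log2 fold change of each tested gene under constitutive DNp63 (horizontal) and induced DNp63 (vertical), grey where called in neither, orange in constitutive only, blue in induced only and black in both. The 32 genes called in both with the same sign lie in the upper right (26) and lower left (6). Most orange points, which were chosen by their constitutive values, lie nearer 0 on the vertical than on the horizontal axis.

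The 2 systems were then compared for the genes they share. Of the 35 genes called under induced DNp63, 32 were called in the same direction under constitutive DNp63, among them CALML3, KRT6A, TRIM29, EDAR and KRT74, which rose, and MOBP, OTOP1 and FZD1, which fell. The 26 shared rises stood against 1.21 for independent lists, and the 6 shared falls against 0.239. These rises include TP63, the overexpressed gene itself. They also count DBH with DBH-AS1 and HOXC13 with HOXC13-AS, partners whose reads cannot be told apart. The systems share no library, and Fisher's exact test across genes gave p = 2.33e-33 and 3.92e-09, as a description, since genes are not independent. The gene CYP24A1, the enzyme that degrades active vitamin D, was called in opposite directions. Apart from it, TP63, DBH, DBH-AS1, MOBP, OTOP1 and FZD1, the genes of this paragraph were chosen for it after their values were seen. HSP90AA1 (1.504 ± 0.20 induced; 0.56, adjusted p = 0.117, constitutive) and the metallothionein gene MT2A (2.23 ± 0.37 induced; 0.56, adjusted p = 0.4, constitutive) were called under induced DNp63 alone, and their differences between systems did not pass the test (adjusted p = 0.206 for each). Without an uninduced or an induced replicate the induced calls of CYP24A1 (adjusted p = 0.184 to 0.362), HSP90AA1 (0.184 to 0.371) and MT2A (0.296 to 0.897) were lost, MT2A was also lost without GFP replicates 1 (0.0517) or 2 (0.0554), and MT2A passed under constitutive DNp63 without DNp63 replicate 1 (0.0144). Of the 1004 genes called under constitutive DNp63, 764 (76.1%) had the same sign under induced DNp63, against 56.5% of all tested genes. The slope of induced on constitutive values over these 1004 genes was 0.257, and choosing them on their constitutive values lowers it. Across the 12303 genes, which are not independent replicates, Pearson's r was 0.383 and Spearman's rho 0.226. The number shared was 5 and 2 without uninduced replicates 1 and 2, 82 and 63 without DNp63 replicates 1 and 2, and 4 without either induced replicate. With each system fitted alone, 139 genes were shared in the same direction and 3 in opposite directions.

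The test of the difference between the systems asked which responses were unequal. CYP24A1 fell with constitutive DNp63, from 41.5 ± 8.05 CPM to 5.92 ± 2.32 CPM (SD, n = 2), and rose with induced DNp63, from 21.4 ± 4.03 CPM to 83.3 ± 6.00 CPM. The difference, induced minus constitutive, was 4.73 ± 0.41 on the log2 scale (adjusted p = 0.00277). The difference was −5.99 ± 0.58 for TP63 (adjusted p = 0.00378) and −4.33 ± 0.47 for KRT6A (adjusted p = 0.00554), which both rose less when induced. FOXQ1, a forkhead transcription factor gene, differed by 2.52 ± 0.25 (adjusted p = 0.00416), with −3.44 constitutive and −0.92 induced. KCNE3, a potassium channel subunit gene, differed by 2.27 ± 0.24 (adjusted p = 0.00456), with −3.41 and −1.14. Ribosomal protein genes, lower under constitutive DNp63, had a median difference of 0.64, with an adjusted p of 2.34e-11 and adjusted p = 0.454 with an estimated correlation. Cholesterol synthesis genes had 1.02 (adjusted p = 1.08e-07, and adjusted p = 0.46 with an estimated correlation) and respiratory chain genes 0.55 (adjusted p = 1.48e-06, and adjusted p = 0.35 with an estimated correlation). The squamous list had −1.60 (adjusted p = 2.18e-05, and adjusted p = 0.187 with an estimated correlation). These are 4 of the 12 lists called for the difference, and the other 8 are given in the next paragraph. For SOX2 and POU3F2 the differences of 1.42 ± 0.40 and 2.49 ± 0.75 did not pass the test (adjusted p = 0.18 and 0.206). SOX2 passed without GFP replicate 1 (0.0256) and POU3F2 without DNp63 replicate 2 (0.0286). Among the genes that differed, 44 had the same sign and a smaller change under induced DNp63, and 23 had opposite signs. Of these 23, only CYP24A1 was called under induced DNp63, so opposite responses are not shown for the others. In total 67 genes differed. The number was 208 and 31 without GFP replicates 1 and 2, 187 and 449 without DNp63 replicates 1 and 2, 3 and 2 without uninduced replicates 1 and 2, and 0 without either induced replicate in edgeR, where 916 and 1230 genes had an unadjusted p below 0.05. DESeq2 called 265 and limma 45 with all 8 libraries. CYP24A1 and TP63 lost their calls without induced replicate 1 (adjusted p = 0.0818 and 0.107) or 2 (0.0602 and 0.0815). FOXQ1 and KCNE3 lost theirs without uninduced replicates 1 (0.0756 and 0.0777) or 2 (0.119 for each) and induced replicates 1 (0.107 and 0.118) or 2 (0.0815 and 0.102). KRT6A lost its call without uninduced replicate 2 (0.119) or induced replicates 1 (0.118) or 2 (0.105).

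Among the other lists that differed between the systems, cell cycle genes had a median of 0.94 (adjusted p = 4.41e-05), histone genes 0.83 (0.00781), antigen presentation genes 0.77 (0.00908) and immediate early genes 0.41 (0.0475). ATF4 stress response genes had −0.85 (4.41e-05), with 24 of 24 members negative, hemidesmosome and basement membrane genes −0.44 (0.0054), p63 targets −0.47 (0.00908) and cornification genes −1.35 (0.0224). With an estimated correlation none of the 12 lists was called. Without GFP replicate 1 the histone call was lost (0.108), and the ATF4 and cornification medians were −1.83 and −0.68. Without GFP replicate 2 the ATF4 (0.266; median −0.12), antigen presentation (0.266), cell cycle (0.143; median 0.25) and immediate early (0.298; median 0.17) calls were lost. The medians there were 0.45 for cholesterol synthesis genes, −0.24 for hemidesmosome genes and −0.71 for p63 targets. Without DNp63 replicate 1 the ATF4 (0.0636; median −0.17), antigen presentation (0.251; median 0.31) and cornification (0.151) calls were lost. Without DNp63 replicate 2 the cell cycle (0.085; median 0.53), hemidesmosome (0.181) and immediate early (0.27) calls were lost, and the ATF4 and antigen presentation medians were −1.34 and 1.56. The immediate early call was also lost without uninduced replicate 2 (0.141) or induced replicates 1 (0.106) or 2 (0.0622), and the cornification call without induced replicate 2 (0.0544). The p63 target median was −0.70 without uninduced replicate 2.

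The control groups, uninduced and GFP cells, were compared to show what differed between the systems without induction. MDM2, a ubiquitin ligase gene, was at 199 and 117 CPM in the GFP libraries and 27.0 and 25.9 CPM in the uninduced libraries. Its log2 difference of −2.58 ± 0.30 (adjusted p = 0.0418) was the only call. The p53 target genes were lower in uninduced cells as a list, with 25 of 26 members negative and a median of −1.26. Of these 1 was called over all genes and 18 adjusted over the list alone, and the list test gave an adjusted p of 3.99e-26 and adjusted p = 0.0224 with an estimated correlation. Among members chosen after their values were seen, the metabolic regulator TIGAR was at 27.8 ± 0.950 CPM (SD, n = 2) with GFP and 6.01 ± 2.23 CPM uninduced, and the death receptor FAS at 7.93 ± 0.764 and 1.78 ± 0.236 CPM. In constitutive DNp63 cells the list medians lay at −0.51 and −0.26 relative to the GFP mean, and in induced cells at −1.51 and −1.33. In each of the 4 pairings of a GFP with an uninduced library, 23 or 24 of the 26 members were lower, with medians from −1.54 to −0.89. ATF4 genes were also lower as a list (median −0.92; adjusted p = 1.49e-05, and adjusted p = 0.453 with an estimated correlation), and without GFP replicate 1 their median was 0.20 (adjusted p = 0.06). Cell cycle genes were higher (median 0.22; adjusted p = 3.47e-05, and adjusted p = 0.453 with an estimated correlation), and without GFP replicate 1 their median was −0.14 (adjusted p = 0.622). Immediate early genes were lower (median −0.45; adjusted p = 4.94e-05, and adjusted p = 0.209 with an estimated correlation). Without GFP replicate 2 the immediate early median was −0.14 and the cell cycle median 0.65. The MDM2 call was lost without uninduced replicates 1 (adjusted p = 0.728) or 2 (1.00) or induced replicates 1 (0.209) or 2 (0.209). Without GFP replicates 1 and 2 the number of genes called was 6 and 45, and without either DNp63 replicate 28. It was 0 without uninduced replicates 1 or 2 (441 and 442 genes at an unadjusted p below 0.05) or induced replicates 1 or 2 (920 and 924) in edgeR, where DESeq2 called 57 and limma 1 with all libraries.

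**Figure D4:**
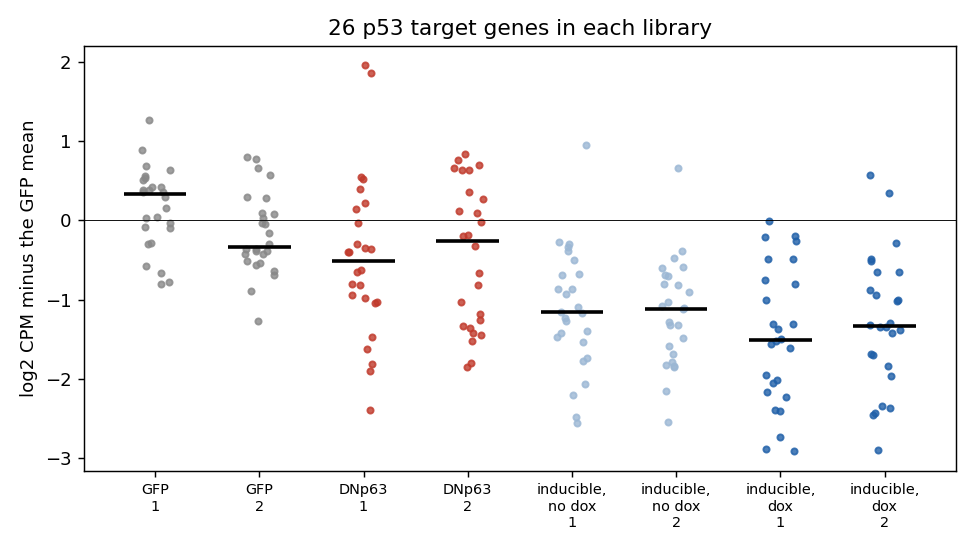
Log2 CPM of the 26 p53 target genes minus their mean in the GFP libraries, with a point per gene in each of the 8 libraries and a bar at the median. The medians are 0.33 and −0.33 with GFP, −1.16 and −1.11 uninduced, −0.51 and −0.26 with constitutive DNp63, and −1.51 and −1.33 induced.

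Of the 25 lists 12 were called between the control groups, 10 downward and 2 upward, and with an estimated correlation only the p53 target list was. Besides the 4 above, histone genes (median −0.71; adjusted p = 0.00108), NRF2 targets (−0.32; 0.00492), hypoxia and glycolysis genes (−0.31; 0.012) and mesenchymal markers (−0.36; 0.0199) were lower in uninduced cells. Squamous markers (−0.65; 0.0199), p63 targets (−0.52; 0.0199) and epithelial junction genes (−0.21; 0.0337) were lower as well, and heat shock genes were higher (0.25; 0.018). Without GFP replicate 1 all of these but the NRF2 targets lost their calls. The adjusted p was then 0.06 for histone genes (median −0.15), 0.0517 for hypoxia genes (−0.19), 0.631 for mesenchymal markers (−0.23), 0.185 for squamous markers (−0.35), 0.185 for p63 targets (−0.12), 0.158 for junction genes (−0.13) and 0.302 for heat shock genes (0.01). Without uninduced replicate 2 the p63 target (0.0653), junction (0.0893) and heat shock (0.129; median 0.09) calls were lost, and the histone and mesenchymal medians were −0.36 and −0.60. Without GFP replicate 2 the junction call was lost (0.0658), and the mesenchymal and heat shock medians were −0.78 and 0.44. The squamous median was −0.27 without uninduced replicate 1.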

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

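Tests of the spread shared by both systems, of the direction of constitutive calls when induced, of the p53 target list and of an ATF4 response were chosen only after the results were seen. Counting the other splits of the libraries was planned, but how that count would be read, with splits balanced over the systems, was chosen after it was seen. Limits given below for the TP63 leak and for the p53 and ATF4 lists are 95% bootstrap limits over genes. Genes are not independent, and these limits do not measure variation between the libraries of a group.

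For 20 genes with values in the text, CDC20 and UNC5B among them chosen after their values were seen, the response differed between the systems in the test of the difference itself, given here as the log2 fold change induced minus constitutive. Rises that were smaller when induced were those of TP63 (−5.99), KRT6A (−4.33), CALML3 (−3.45), UNC5B (−3.08), ITGA3 (−1.97) and PLEC (−1.73), and of the low-count genes PDE7B (−8.70) and AK8 (−6.00), whose fitted values depend on groups with 3 or fewer counts. Falls that were smaller when induced were those of ADH1C (3.88), HAS3 (2.88), ALDH3A1 (2.63), FOXQ1 (2.52), FZD1 (2.38), FOXA2 (2.30), KCNE3 (2.27) and, at 3 counts with constitutive DNp63, GRIK3 (5.65). The anaphase activator CDC20 had a difference of 1.90, the Notch modifier LFNG of 1.68 and the immediate early gene JUN of 1.62. All of them fell under constitutive DNp63, and their induced log2 fold changes of 0.55, −0.02 and 0.24 were not called. CYP24A1 had 4.73 and was called in opposite directions. Without GFP replicate 2 the differences of CDC20 (adjusted p = 0.0543), FOXA2 (0.0543), PLEC (0.0791) and ITGA3 (0.104) were not called. No sample was tested as an outlier, since groups of 2 cannot be, and no deposited data stood outside the comparisons. Without uninduced replicate 1 or 2 the number of genes that differed was 3 or 2, and without either induced replicate it was 0 in edgeR (916 and 1230 genes at an unadjusted p below 0.05).

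Fewer genes were called under induced (35) than under constitutive DNp63 (1004). Fitted with its own 4 libraries, the inducible system gave 803 calls and the constitutive system 282. The common dispersion was 0.0103 and 0.0817 in these fits, against 0.0448 for all 8 libraries. A spread shared by both systems may thus account for much of the low induced count and for part of the high constitutive count. The constitutive adjusted p values may be too small for the same reason. Replicates of a constitutive group carry different vector numbers, while all inducible libraries share the same vector number. The larger constitutive spread may therefore hold a difference between vectors, which cannot be told apart from replicate variation. Smaller changes of the same genes may contribute, since 76.1% of constitutive calls had the same sign when induced. The slope of 0.257 cannot decide this, because choosing genes on their constitutive values lowers it. In the test of the difference, 44 of 67 called genes had the same sign and a smaller induced change. The other 23 had opposite signs, but of these only CYP24A1 was called under induced DNp63. Vector and doxycycline also differed between the systems, so the lower TP63 level cannot be singled out as the reason. For a TP63 leak in uninduced cells, genes called higher with 1 GFP library were measured against the other. Against GFP replicate 2, these genes were shifted in uninduced cells by a share of 0.038 of their constitutive change (upper limit 0.0842). Against GFP replicate 1, which stood apart as described below, the share was −0.247. These shares argue against a leak alone. Since the comparison crosses the systems, it cannot exclude a leak together with another difference between them. The shared spread and smaller changes of the same genes stay open together.

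The p53 target list was lower in uninduced than in GFP cells, by a median of −1.26. A TP63 leak alone would need constitutive DNp63 cells to hold the list as low or lower. They held it higher than uninduced cells, by a median of 0.60 (bootstrap limits over genes 0.13 to 1.17). Since this comparison crosses the systems, it cannot exclude a leak together with another difference between them. Scaling between systems is argued against by the list's distance from the median of all genes, which was −1.25 under the scaling that brought it closest to 0. Induced cells were also lower than constitutive DNp63 cells (median −0.77, bootstrap limits over genes −1.44 to −0.29). Vector, selection or culture of the system therefore stays a candidate explanation. It cannot be told apart from any other difference between the systems, because each vector occurs in 1 system.

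GFP replicate 1 and DNp63 replicate 1 stood apart, with 42 genes at least 2-fold higher and 7 lower in both than in each of the other 6 libraries, among them SNHG1, EIF3E and CEBPB (chosen after their values were seen), while other pairs from different groups had at most 10 in a direction. Reads shared with other genes may account for a part, since the genes higher in both had mostly shared 38-base stretches more often than other genes (9 of 40 against 633 of 12055, odds ratio 5.24, limits 2.18 to 11.3), but 31 of the 40 were mostly of their own sequence. A shared ATF4 stress response may contribute, since that list was higher in replicate 1 by a median of 1.12 with DNp63 (0.76 to 1.23) and 1.71 with GFP (1.19 to 2.26). Reads from processed pseudogenes stay open at an odds ratio of 1.09 (0.408 to 2.52), and so does lower depth, as 65.3% of the 49 genes stayed apart after thinning to equal totals. Both libraries also share a vector number, which was not tested as a cause.

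For the averaged comparison the real split of the libraries into 4 and 4 gave 697 calls against 67 in the highest of the other 33 splits that could be fitted. Like the real one, 18 splits put 2 libraries of each system on each side, of which 1, the real split, gave as many calls, and these are too few for a share under 0.05. The highest other set GFP and induced libraries against uninduced and constitutive DNp63 libraries. That is the contrast of the difference between the systems, which also called 67 genes, so its number is not a chance level. Every remaining split put control and DNp63 libraries of a system on the same side. The DNp63 effect then entered the spread, which by itself lowers the number of calls. The count of splits therefore cannot show how many calls would arise by chance.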

How the results depend on the processing

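Leaving out both first-numbered constitutive libraries and the newer edgeR estimates were chosen after seeing the data, and so were 101 of the 240.0 gene results below. TP63 kept its call in the averaged comparison under every alternative that could give it a value, with log2 fold changes of 7.10 (additive model) to 8.39. Of 175 called gene results, 175 held under median-of-ratios scaling, 168 under library totals, 175 without a filter, 159 of the 169 still measured under the strict filter, 174 in DESeq2, 157 in limma, 174 of 174 with the block and 95 to 167 with 1 library left out. Of the 70 called in the averaged comparison 41 held in an additive model and 16 in a model with no term for the system, and of the 63 called under constitutive DNp63 43 held with the constitutive libraries fitted alone. With a minimum log2 fold change of 1, 150.0 of the 175 held, 173 with the newer edgeR estimates, 171 without both first-numbered constitutive libraries, 171 of 171 with TP63 left out of the library sizes, and 28 of 28 induced results with the inducible libraries fitted alone. None changed direction in a call under these alternatives. Of the 65 gene results not called, 36 were called without a filter, 21 each in DESeq2, with the block and without DNp63 replicate 2, 17 without GFP replicate 1, 10 without DNp63 replicate 1, 5 each under library totals and in limma, 4 without GFP replicate 2, 1 under the strict filter, 49 without both first-numbered constitutive libraries, 6 with the newer edgeR estimates, 3 with the inducible libraries alone, 1 in the additive model, and none under median-of-ratios scaling or without an uninduced or induced library. Of 59 called list results, 59, 59, 54, 57, 58 and 53 held under median-of-ratios scaling, library totals, no filter, the strict filter, DESeq2 and limma, in that order, and 4 with an estimated correlation, which left 1 of 13 lists called in the averaged comparison. With the block, which leaves out the control groups, 46 of 47 called list results held and 2 uncalled ones were called.

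The lowest and highest numbers of calls with 1 library left out were 224 and 1112 for the averaged comparison, 451 and 1398 for constitutive, 2 and 100 for induced DNp63, 0 and 449 for the difference, 0 and 45 for the control groups and 2 and 82 for genes shared by both systems. Each leave-out also changes the weight of the 2 systems in the shared spread, and their replicates vary unequally. The part of this in the numbers was not tested separately. Without a filter the calls were 1372 averaged, 1791 constitutive, 242 induced, 558 for the difference, 245 between controls and 169 shared; the cause was not tested. With the strict filter the controls had 0 in edgeR, where 915 genes had an unadjusted p below 0.05. DESeq2 gave 110 induced, 265 for the difference, 57 between controls and 83 shared, and limma 26, 45, 1 and 23; the cause was not tested. A minimum log2 fold change of 1 left 437 in the averaged comparison by its construction. A model with no term for the system gave 69 and an additive model 283, whose construction puts differences between systems into the spread. Fitted alone, the constitutive libraries gave 282 and the inducible ones 803. Without both first-numbered constitutive libraries the calls were 2847, 2861, 821, 1692, 965 and 451 in the same order as without a filter; the cause was not tested. Under library totals the constitutive calls were 604 higher and 358 lower (62.8% higher, against 51.1%), and the median of all genes in the difference was −0.11, against −0.01.

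With each numbered pair within a system as a replicate block the calls were 1040.0 averaged (697 without it), 1400.0 constitutive (1004), 87 induced, 270 for the difference and 76 shared; the cause was not tested. The control groups cannot be tested with this block, since each pair lies in 1 system. Paired constitutive libraries share a vector number and paired inducible libraries a replicate number alone, and their deviations correlated at 0.22 and −0.03. Between controls, the ATF4 list turned from −0.92 to 0.20 without GFP replicate 1 (−1.18 without GFP replicate 2) and to 0.21 without both first-numbered constitutive libraries, and the cholesterol list from −0.14 to 0.41 without GFP replicate 2 (−0.50 without GFP replicate 1); the cause was not tested. Totals of 2758158 to 10372248 counts limit what could be called among weakly expressed genes.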

Other observations

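Of the genes called in both systems, KRT74, HOXC13 and SP6 belong to no list and were chosen after their values were seen, and genes of hair, teeth or nail were not tested as a group. KRT74, a keratin of the hair follicle's inner root sheath, rose by 2.94 ± 0.24 (SE, log2, n = 2 per group) under constitutive and 3.40 ± 0.23 under induced DNp63, from 10.8 ± 2.15 to 84.4 ± 3.07 CPM (SD, n = 2) and from 10.9 ± 0.854 to 116 ± 18.3 CPM. HOXC13, a transcription factor of hair and nail, rose by 2.59 ± 0.37 and 2.60 ± 0.37, although its reads cannot be told from those of its antisense partner HOXC13-AS. SP6, a transcription factor of teeth and skin appendages, rose by 3.85 ± 0.37 and 3.13 ± 0.35. EDAR, the receptor for ectodysplasin in hair and tooth development and a member of the p63 target list, had 6.51 ± 0.62 and 3.12 ± 0.47. KRT74 kept both calls with each library left out. The constitutive calls of the other 3 held too, but their induced calls were lost without uninduced replicates 1 (adjusted p from 0.149 for SP6 to 0.424 for EDAR) or 2 (0.171 for SP6 to 0.498 for HOXC13) or induced replicates 1 (0.137 for SP6 to 0.308 for EDAR and HOXC13) or 2 (0.0983 for SP6 to 0.238 for EDAR).

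The genes of this paragraph, also called in both systems, were chosen after their values were seen. SLC7A8, a transporter of neutral amino acids, rose from 30.9 ± 2.98 to 330.3 ± 11.0 CPM under constitutive DNp63 (3.41 ± 0.20 on the log2 scale) and from 29.05 ± 1.90 to 137 ± 1.35 CPM under induced DNp63 (2.24 ± 0.18). The kinase gene SGK1 rose by 4.37 ± 0.51 and 3.42 ± 0.54, and the netrin receptor gene UNC5B by 5.60 ± 0.43 and 2.52 ± 0.37, a called difference of −3.08 ± 0.53 (adjusted p = 0.0374). That call was lost without uninduced replicates 1 (0.2) or 2 (0.247) or induced replicates 1 (0.277) or 2 (0.216). The matrix gene EFEMP1 rose by 6.11 ± 0.48 and 3.41 ± 0.51, DKK3, of the Dickkopf family, by 4.99 ± 0.51 and 3.20 ± 0.45, and SERPINF1, which encodes an inhibitor of vessel growth, by 3.18 ± 0.45 and 2.51 ± 0.42. GALNT10, an enzyme of O-glycosylation, had −1.74 ± 0.19 and −1.35 ± 0.18. The induced call of SLC7A8 was lost without uninduced replicate 2 (adjusted p = 0.0757) and that of SGK1 without GFP replicate 2 (0.0521). The induced calls of SGK1, UNC5B, EFEMP1, DKK3, SERPINF1 and GALNT10 were lost without uninduced replicates 1 (0.246 to 0.498) or 2 (0.311 to 0.934) or induced replicates 1 (0.296 to 0.374) or 2 (0.184 to 0.306), while their constitutive calls held in each.

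The nuclear RNA MALAT1, chosen after its values were seen, was at 57.0 and 66.1 CPM uninduced and 120 and 76.7 CPM induced. Variation between the 2 replicates, as a chi-square per degree of freedom against counting error, was 19.2 with GFP, 26.7 with constitutive DNp63, 3.93 uninduced and 5.41 induced. The replicates of each constitutive group carry different vector numbers, while all inducible libraries share the same vector number. The constitutive values therefore include any difference between vectors, which cannot be told apart from replicate variation. The first dimension of a multidimensional scaling plot held 50.7% of the variation and set the constitutive DNp63 libraries apart from the other 6, and the second held 16.4%.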
